A study of Ovis aries with 23 samples.

How the data were processed

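The authors deposited a table in log2 with 8411 probes for the 23 arrays. It was normalized between arrays, in a way not stated, with array medians of 9.267 to 9.305. The authors' notes name limma without a version. The raw files, in intensity units per the file headers and column names, came from Feature Extraction 10.1.1.1 with a 1-colour protocol. Their processed signal was background-subtracted and detrended on each array, with no normalization between arrays. The main values here were made from that signal, and the deposited table was used as an alternative. The series text gives another array design number and scanner model than the file headers do.

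Each array held 15744 spots, of which 536 were controls. The 15208 other spots formed 15008 probes, 50 of them with 5 spots. Spots marked as outliers by the scanner software were left out, and the spots of a probe were averaged on the log2 scale. Each array's 75th percentile was subtracted. A probe was tested if it was well above background, by the software's own test, on at least 2 arrays of at least 1 group, which kept 12451. At most 1 probe had a saturated spot on any array.

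Names came from the reference table and the file's own columns. Of 15008 probes 13308 carried an accession only. A name was given to 694 by accession, 125 by gene ID, 529 by symbol, 20 by an older symbol, 167 by the file's own name, 114 by the array's name updated by hand and 44 by the protein in the description. In 7 cases the accession and the description named different genes, and the probe was left unnamed. These 1693 probes stood for 1033 names, 578 of them with more than 1 probe and 72 probes with a LOC number. A gene was represented by its brightest tested probe, which gave 853 genes. The genes NPPA, NPPB, MYH6, POSTN, TNC, CCL2, CD163, S100A8, MKI67 and HMOX1, to be named in any case, were not named on the array, and SPP1 was not tested. Some of the genes and 1 of the gene lists tested are not reported here.

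One limma model (R 4.3.3, limma 3.58.1) was fitted to all 8 groups with empirical Bayes variances. Comparisons were contrasts of it, and age differences were differences of contrasts. P-values were adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05. The origin of the replicates is not stated, nor is whether the zones of 1 number came from 1 animal. The p-values therefore measure the spread between these samples, which may be technical. Groups of 1 remaining array, when adolescent sham lost 1, were assumed to vary like the others.

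Whether replicate numbers pair was checked by correlating each array's deviations from its group mean. Arrays of 1 number had a mean correlation of 0.138 and those of other numbers −0.069. Deviations within a group cancel out, so the second value is tied to the first and adds no evidence. In the fetal comparisons every pair was positive, with infarct and sham at 0.235, 0.109 and 0.192, border and sham at 0.283 to 0.332, remote and sham at 0.318 to 0.574 and infarct and remote at 0.156 to 0.315. In the adolescent comparisons with sham the lowest were −0.033, −0.085 and 0.095, in adolescent infarct and remote 0.034, and between the shams 0.078. Numbers were taken to pair in the 4 fetal comparisons by a rule that every correlation of at least 3 pairs exceeds 0.1.

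Of 35 gene lists, 27 had at least 3 measured members and were tested over the 853 genes with camera at a preset correlation of 0.01, with 6 missing values filled with the group mean. Each list was also tested with an estimated correlation, under which none of the 68 calls among 324 tests held, and with fry, which tests whether a list's genes move 1 way and does not compare it with other genes. Fry called 80. The lists of sarcomere, calcium handling, tricarboxylic acid cycle, B cell, smooth muscle, myofibroblast, epicardial and Schwann cell genes had fewer than 3 measured members and were not tested.

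Genes were named by a rule. The 6 highest and 6 lowest fold changes past the threshold with 1 sign on every slide were taken in each infarct against sham comparison. In the other zone comparisons and between the shams 4 and 4 were taken, and in each age difference 5 and 5. Up to 4 members of each list described, by moderated t, and a fixed set of 25 genes were added. Where no probe of a gene was well above background on any array of a group, a fold against that group is a bound, written "at least". For it, each value of that group was raised to the lowest signal called well above background on its array. In age differences adolescent sham was raised in this way. For calls of named genes above background on only some arrays of a group, the size with every array not above background so raised is given as "at the limit" where it moved by over 0.2 log2.

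Recovery was tested with 200 of 12451 probes changed and no other group difference. In fetal infarct against sham 32% of 2-fold and 86% of 4-fold changes were recovered, and 11 of 129 calls were unchanged probes. In adolescent infarct these were 20%, 77% and 6 of 103, and in the age difference 5%, 53% and 6 of 64. Each list test called 11 genes shifted by 1 log2 in 20 of 20 runs and none of 540 unshifted lists. With more calls in the data, this may not hold there or for lists of correlated genes.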

Results

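Transcript levels were measured in the left ventricle of fetal sheep at 105 days of gestation and of adolescent sheep at 6 months of age. The infarcted hearts were taken 3 days after a coronary branch had been tied off, and those after sham surgery at a time not stated. From the infarcted hearts, tissue of the infarct itself, of the border around it and of remote muscle was sampled. The 23 arrays formed 8 groups, with 3 arrays in each group except adolescent sham, which holds 2 (replicates 2 and 3). Each sample was labelled with Cy3 and read in 1 colour on a sheep array with 15008 different probes, of which 12451 passed the filter and were tested. Named genes could be assigned to 1693 of the 15008 probes, so the genes described here, 853 of them tested, are a small part of what was measured. The number of arrays limits the precision of every value.

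Signal strength differed between the groups. The 75th percentile of the background-subtracted signal, in intensity units, lay between 477.6 and 853.6 on the 12 fetal arrays. It was 242.9 and 128 on the adolescent sham arrays, 303.8 to 369.7 on the adolescent remote arrays, 664.5, 517 and 228.2 on adolescent border 1, 2 and 3 and 750.1 to 1330 on the adolescent infarct arrays. The share of probes well above background ran from 60.99% on adolescent sham 3 to 83.76% on fetal sham 1. Each replicate number was 1 slide, and the position on the slide coincided with the group, so position and group cannot be told apart. Values are log2 signals after each array's 75th percentile was subtracted. Errors are standard errors (SE) of the limma fit, and p-values are two-sided and adjusted over the 12451 probes, except for list tests.

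Fetal infarct tissue was compared with fetal sham tissue to ask how a heart before birth responds to infarction (n = 3 and 3). Transcripts of inflammation and of phagocytes were higher in the infarct. IL6, a cytokine of acute inflammation, was 75.1-fold higher (log2 6.23 ± 0.98 SE, adjusted p = 0.00157), above background on 1 of 3 sham arrays and 31.7-fold at the limit, that is with the other 2 raised to the background limit. SLC11A1, a metal transporter of phagosomes, was 47.3-fold higher (log2 5.56 ± 1.11, adjusted p = 0.00362), and SLC2A5, a fructose transporter, 30.5-fold (4.93 ± 0.98, adjusted p = 0.00354). LOC443321, described on the array as a lysozyme, was 29.6-fold higher (4.89 ± 1.20, adjusted p = 0.0109), PLAUR, the urokinase receptor, 21.5-fold (4.43 ± 0.76, adjusted p = 0.00187) and S100A4, a calcium-binding protein of motile cells, 20.8-fold (4.38 ± 0.83, adjusted p = 0.0028). At the threshold of 0.05, 1177 probes were higher and 954 lower, 2131 in all, among them 124 and 54 named genes. Leaving out 1 array took the count to 820 without fetal infarct 3, to 1112 without fetal sham 3 and to 1215 without fetal sham 1, and the call of LOC443321 ended without fetal infarct 3 (adjusted p = 0.0738). With normexp background correction (offset 50, not tested apart) the count was 189. Of 56 calls of named genes and list members 39 ended, IL6, SLC2A5, LOC443321 and PLAUR among them. In the deposited values SLC2A5 missed the threshold (log2 1.59, adjusted p = 0.0666).

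The cytokine and chemokine list rose in fetal infarct tissue. Of its 14 measured members, 9 were higher and 5 did not pass the test over all probes, with 9 also when adjusted over the list alone, and the list median was 2.20 log2 (camera, adjusted p = 0.000113). With an estimated correlation the lists called in fetal infarct had adjusted p = 0.414 or 0.473. IL1A was 14-fold higher (log2 3.80 ± 0.55, adjusted p = 0.00151), IL10, which restrains inflammation, 9.64-fold (3.27 ± 0.50, adjusted p = 0.00157) and IL18 5.43-fold (2.44 ± 0.35, adjusted p = 0.00141). CXCL8, which draws neutrophils, was 11-fold higher (3.47 ± 0.93, adjusted p = 0.0172) and IL1B 3.91-fold (1.97 ± 0.52, adjusted p = 0.0159). The call of CXCL8 ended without fetal infarct 1 or 3 or fetal sham 1 or 3 (adjusted p = 0.0531 to 0.0797), and that of IL1B without fetal infarct 1 or 3 or fetal sham 2 or 3 (0.0507 to 0.0713). Normexp correction ended all 5 of these calls. Over probes well above background on every array, the list was not past the threshold (adjusted p = 0.146).

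Markers of macrophages and monocytes rose as well. Of 8 members 7 were higher, 7 also when adjusted over the list alone, with a median of 2.88 log2, or 2.77 with members against background at their bound (camera, adjusted p = 7.61e-05). LGMN, a lysosomal protease, was 6.64-fold higher (log2 2.73 ± 0.46, adjusted p = 0.00175), CD14, a coreceptor for bacterial lipopolysaccharide, 7.69-fold (2.94 ± 0.50, adjusted p = 0.00176) and FCER1G, an Fc receptor chain, 8.35-fold (3.06 ± 0.55, adjusted p = 0.00212). Of 13 acute phase and innate sensing members 6 were higher, 7 when adjusted over the list alone, with a median of 1.68 log2, or 1.21 at the bounds (camera, adjusted p = 0.000859). TLR2 was 9.66-fold higher (3.27 ± 0.75, adjusted p = 0.00796) and PTGS2, a prostaglandin synthase, 4.52-fold (2.18 ± 0.43, adjusted p = 0.00354). Of 5 antigen presentation members 3 were higher, 3 also when adjusted over the list alone, with a median of 1.33 log2 (camera, adjusted p = 0.0161). CTSS, a cathepsin that trims the invariant chain, was 11.5-fold higher (3.52 ± 0.59, adjusted p = 0.00175). The innate sensing list was not past the threshold with normexp correction (adjusted p = 0.499) or over probes well above background on every array (adjusted p = 0.0964), and normexp correction also ended the calls of CD14, TLR2 and PTGS2.

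Matrix genes were higher too. Of 11 extracellular matrix members 5 were higher, 7 when adjusted over the list alone, with a median of 1.63 log2 (camera, adjusted p = 0.00233). COL12A1 was 5.60-fold higher (log2 2.49 ± 0.41, adjusted p = 0.00165), and COL1A1, a chain of the main fibrillar collagen, 4.09-fold (2.03 ± 0.50, adjusted p = 0.0106), with its call ending without fetal sham 3 (adjusted p = 0.0568). COL3A1 was not past the threshold (1.22 ± 0.66, adjusted p = 0.214). Of 13 matrix proteases and inhibitors 9 were higher, 11 when adjusted over the list alone, with a median of 1.56 log2, or 1.34 at the bounds (camera, adjusted p = 7.59e-05). TIMP1, an inhibitor of matrix proteases, was 7.40-fold higher (2.89 ± 0.65, adjusted p = 0.00686) and CTSB, a lysosomal cathepsin, 5.81-fold (2.54 ± 0.51, adjusted p = 0.0038). Of 6 fibroblast markers 3 were higher, S100A4, COL1A1 and VIM, with 5 when adjusted over the list alone and a median of 1.43 log2 (camera, adjusted p = 0.0161). VIM, an intermediate filament protein, was 2.14-fold higher (SE 0.30 log2, adjusted p = 0.0173), and its call ended without fetal infarct 1 (adjusted p = 0.0658) or fetal sham 3 (0.0625) and with normexp correction.

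Energy lists except glycolysis fell in fetal infarct. Of 7 fatty acid oxidation members 1 was lower, 4 when adjusted over the list alone, with a median of −0.77 log2 (camera, adjusted p = 0.0311). CPT1B, which carries fatty acids into mitochondria, was 3.44-fold lower (log2 −1.78 ± 0.37, adjusted p = 0.00492), not past the threshold with normexp correction. PPARGC1A, a regulator of mitochondrial genes, missed the threshold (−1.90 ± 0.75, adjusted p = 0.089) and passed it without fetal infarct 1 (adjusted p = 0.0383), with quantile normalization (0.0442) and in the deposited values (0.0127). The list missed the threshold without fetal infarct 2 (adjusted p = 0.0597), without fetal sham 1 (0.0747) and with the number as a block (0.0525). It also missed it over probes well above background on every array (0.0591) and against unnamed probes (0.0727). Of 5 oxidative phosphorylation members 2 were lower, 3 when adjusted over the list alone, with a median of −0.68 log2 (camera, adjusted p = 0.0161). ATP5MC1, a subunit of ATP synthase, was 1.66-fold lower (−0.73 ± 0.21, adjusted p = 0.0239). That call ended without fetal infarct 3 (adjusted p = 0.134), fetal sham 1 (0.081) or fetal sham 2 (0.055), and the list missed the threshold without fetal infarct 3 (adjusted p = 0.0519) and with normexp correction (0.359). Of 10 glycolysis members 1 was higher and 2 lower, 1 and 4 when adjusted over the list alone, and the list was not past the threshold (median −0.27, adjusted p = 0.206). SLC2A4, the insulin-regulated glucose transporter, missed the threshold (−1.85 ± 0.68, adjusted p = 0.0683), as did MYH7, a myosin heavy chain (−1.10 ± 0.65, adjusted p = 0.263). SLC2A4 passed it without fetal infarct 1 (adjusted p = 0.0311), with quantile normalization (0.0495), in the deposited values (0.0135) and over probes well above background on every array (0.0463).

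Of 11 cell cycle members 3 were higher in fetal infarct, 3 also when adjusted over the list alone, and the list was not past the threshold (median 0.60 log2, camera, adjusted p = 0.102). It passed without fetal sham 3 (adjusted p = 0.0152), without a filter (0.0394) and against unnamed probes (0.0149). TYMS, a thymidylate synthase of DNA replication, was 2.66-fold higher (log2 1.41 ± 0.31, adjusted p = 0.00669), a call that ended with normexp correction. CCNB1, a mitotic cyclin, was 2.37-fold higher (1.24 ± 0.37, adjusted p = 0.0277), and its call ended without fetal infarct 2 or 3 or fetal sham 1 (adjusted p = 0.0525 to 0.119) and with normexp correction. CDK1 missed the threshold (0.86 ± 0.36, adjusted p = 0.106) and passed it in the deposited values (adjusted p = 0.00333). VEGFA, the vascular growth factor, was not past it (−0.82 ± 0.54, adjusted p = 0.318).

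Of the 6 lowest named genes in fetal infarct 4 were of proteins made in the liver. AHSG, a plasma glycoprotein, was 366-fold lower than in fetal sham (log2 −8.52 ± 1.33, adjusted p = 0.00157, 310-fold at the limit), ALB, serum albumin, 52.8-fold (−5.72 ± 1.13, adjusted p = 0.00342) and SERPINA1, an elastase inhibitor, 43-fold (−5.43 ± 1.42, adjusted p = 0.0148, 24.6-fold at the limit). SPP2 was at least 8.88-fold lower (adjusted p = 0.00669). FBP2, a fructose bisphosphatase of muscle, was at least 3.1-fold lower (adjusted p = 0.00355) and CHIA, a chitinase, at least 1.31-fold (adjusted p = 0.0424). The high AHSG levels belonged to the fetal sham arrays. AHSG stood at 7.29, 0.25 and 2.53 log2 on fetal sham 1, 2 and 3, while its mean over the fetal zone arrays was −5.49. Over 5 other liver transcripts, fetal sham was a median of 1.25 log2 above the fetal zones, and 0.43 above them without fetal sham 1. The call of SERPINA1 ended without fetal sham 1 (log2 −3.33, adjusted p = 0.0773) or fetal infarct 3 (adjusted p = 0.0698) and in the deposited values (log2 −1.86, adjusted p = 0.0511). That of CHIA ended without fetal infarct 1, 2 or 3 or fetal sham 1 or 3 (adjusted p = 0.0529 to 0.165) and without a filter (0.0549). Normexp correction ended the calls of SERPINA1, SPP2, FBP2 and CHIA, and a fit of these groups alone ended those of ALB, SERPINA1, SPP2 and CHIA (adjusted p up to 0.0858).

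The other lists were not past the threshold in fetal infarct. Of 3 complement members 1 was higher, C5AR1, a receptor on phagocytes, with 2 when adjusted over the list alone (camera, adjusted p = 0.432). Of 16 developmental signalling members 2 were higher and 1 lower (adjusted p = 0.643), with 4 higher and 3 lower when adjusted over the list alone. The antioxidant and adipocyte lists had adjusted p = 0.863. Of 4 neutrophil markers ITGB2, an integrin chain shared by leukocytes, was 14.9-fold higher (3.90 ± 0.71, adjusted p = 0.00232), and the list median was −0.60 against a mean of 0.45 and an upward test (adjusted p = 0.863). Of 5 T and NK cell markers 1 was higher, with a median of −0.23, a mean of 0.09 and a downward test (adjusted p = 0.945). No member was past the threshold over all probes in the fetal gene programme (4 members, adjusted p = 0.575), interferon response (5, 0.863), hypoxia (4, 0.643), heat shock (8, 0.769) and angiogenesis (13, 0.206) lists. The same held for markers of mast cells (3, 0.206), endothelium (7, 0.146), erythroid cells (4, 0.429) and skeletal muscle (4, 0.643). The interferon list had a median of −0.10 with a mean of 0.18 and an upward test, and the developmental list a median of −0.32 with a mean of 0.14 and a downward test.

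**Figure D1:**
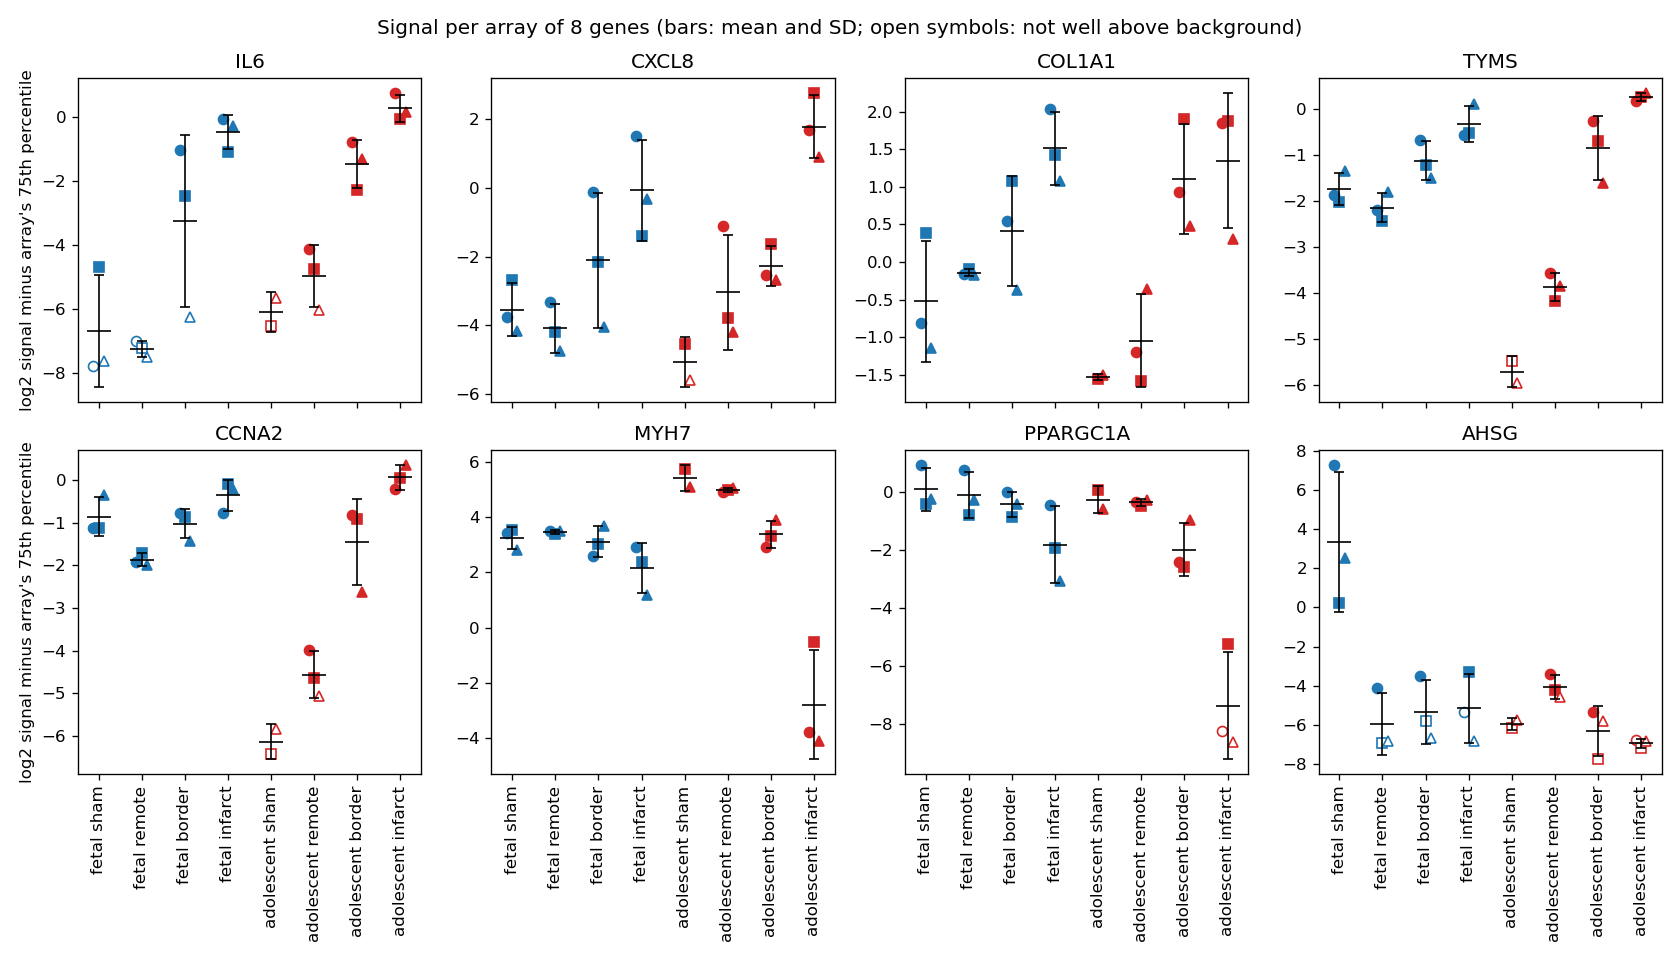
Log2 signal minus the array's 75th percentile (y axis) on each array for 8 genes, by group (x axis), with circles, squares and triangles for slides 1, 2 and 3, open symbols for arrays where the probe was not well above background, and bars for the mean and SD. AHSG stood at 7.29, 0.25 and 2.53 on the fetal sham arrays, and MYH7 was 294-fold lower in adolescent infarct than in adolescent sham.

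Fetal border tissue was compared with fetal sham (n = 3 and 3) to ask how far the response spreads around the infarct. Only 2 probes passed the threshold, both for AHSG, and both were lower (log2 −8.71 ± 1.33 and −9.13 ± 1.45, adjusted p = 0.0418 for each, the first −8.40 at the limit), while 934 probes had an unadjusted p under 0.05. Without fetal border 2 or fetal sham 3 the count was 0, without fetal sham 2 it was 13 and without fetal border 3 it was 125, and with array weights it was 1027. The AHSG call ended without fetal border 2 (adjusted p = 0.407) or fetal sham 3 (0.167), without a filter (0.0563), in the deposited values (0.17), with normexp correction (adjusted p = 1), with array brightness in the fit (0.0872) and in a fit of these groups alone (0.646).

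Inflammation and matrix lists were nevertheless higher as groups in fetal border, with no member past the threshold over all probes. The medians were 1.56 log2 for macrophage markers (camera, adjusted p = 1.92e-05), 1.03 for cytokines and 0.74 for proteases (the same adjusted p), 0.63 for antigen presentation (adjusted p = 0.00188), 0.67 for extracellular matrix (0.00453), 0.47 for innate sensing (0.0116) and 0.77 for fibroblast markers (0.0125). With an estimated correlation these had adjusted p = 0.319 to 0.635, and fry called none (adjusted p = 0.0835 to 0.33). Adjusted over the list alone, 7 of 8 macrophage markers, 4 of 14 cytokines, 2 of 13 proteases, 2 of 5 antigen presentation genes, 1 of 13 innate sensing genes and 1 of 6 fibroblast markers were higher. Without fetal border 2 the matrix and fibroblast lists (adjusted p = 0.0693 for both) and the innate sensing list (0.0673) missed the threshold, and without fetal border 1 the innate sensing list missed it (0.207). The innate sensing list also missed it in the deposited values (adjusted p = 0.104), with normexp correction (0.62) and over probes well above background on every array (0.108).

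In remote muscle of infarcted fetal hearts against fetal sham (n = 3 and 3), 2 probes passed the threshold. Both were of AHSG, and both were lower (log2 −9.31 ± 1.33, adjusted p = 0.0206, −8.41 at the limit, and −9.61 ± 1.45, adjusted p = 0.022), and 218 probes had an unadjusted p under 0.05. With the replicate number as a block 4 probes passed. The count was 0 without fetal remote 2, fetal remote 3 or fetal sham 3 and 13 without fetal sham 2. Without fetal remote 2, fetal remote 3 and fetal sham 3 in turn, AHSG had adjusted p = 0.232, 0.118 and 0.0829. It also missed the threshold in the deposited values (adjusted p = 0.19), with normexp correction (0.257) and in a fit of these groups alone (adjusted p = 1). The cell cycle list fell, with a median of −0.65 log2 over 11 members, none past the threshold over all probes or adjusted over the list alone (camera, adjusted p = 3.65e-07, adjusted p = 0.471 with an estimated correlation, and 0.992 by fry). Without fetal remote 1 that list missed the threshold (adjusted p = 0.0755).

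Set against remote muscle of the same age (n = 3 and 3), fetal infarct tissue was again higher in transcripts of inflammation. IL6 was at least 29.7-fold higher (adjusted p = 0.00174), SLC2A5 at least 33.8-fold (adjusted p = 0.0029), SLC11A1 38.3-fold (log2 5.26 ± 1.11, adjusted p = 0.00556) and PLAUR 24.9-fold (4.64 ± 0.76, adjusted p = 0.00255). Lower were NGN3, the transcription factor neurogenin 3, at least 1.02-fold (adjusted p = 0.0327), PLIN5, a lipid droplet protein of muscle, 4.42-fold (−2.14 ± 0.65, adjusted p = 0.0307), FBP2 at least 1.83-fold (adjusted p = 0.0182) and SLC2A4 4.27-fold (−2.09 ± 0.68, adjusted p = 0.0414). In all 2169 probes passed, 1194 higher and 975 lower, with 727 without fetal infarct 3, 1172 without fetal remote 3 and 140 with normexp correction. That correction ended the calls of IL6, SLC2A5, NGN3, PLIN5, FBP2 and SLC2A4 and turned NGN3 to 0.08. SLC2A5 (adjusted p = 0.0603) and PLIN5 (0.0547) missed the threshold in the deposited values, and FBP2 and SLC2A4 (adjusted p up to 0.0733) in a fit of these groups alone. SLC2A4 also missed it without a filter (0.0533) and with array brightness in the fit (0.0627).

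The 4 lower genes also rested on single arrays. Each call ended without fetal infarct 2, fetal infarct 3 or fetal remote 1, with adjusted p = 0.0929 to 0.139 for NGN3, 0.0587 to 0.144 for PLIN5, 0.0549 to 0.0898 for FBP2 and 0.105 to 0.185 for SLC2A4. Without fetal remote 3 those of NGN3, PLIN5 and SLC2A4 ended (0.0615 to 0.0821), and without fetal remote 2 that of SLC2A4 (0.0771).

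Here the cell cycle list was past the threshold, with 6 of 11 members higher, 8 when adjusted over the list alone, and a median of 1.45 log2 (camera, adjusted p = 0.000609, and adjusted p = 0.402 with an estimated correlation). It missed it over probes well above background on every array (adjusted p = 0.0612). Higher members numbered 9 of 14 cytokines, 7 of 13 proteases, 7 of 13 innate sensing genes, 7 of 8 macrophage markers, 5 of 11 matrix genes, 3 of 5 antigen presentation genes and 4 of 6 fibroblast markers, with 9, 11, 8, 7, 6, 3 and 5 when adjusted over the list alone. The lists of fatty acid oxidation (2 of 7 lower, 3 alone), oxidative phosphorylation (3 of 5, 5 alone) and glycolysis (4 of 10, 5 alone) fell. Camera gave these lists adjusted p = 0.000169 to 0.048, and with an estimated correlation adjusted p = 0.402 or 0.411. The glycolysis list (0.048) missed the threshold without fetal infarct 2 or 3 or fetal remote 2 or 3 (0.0544 to 0.177), the fatty acid list (0.0366) without fetal infarct 2 (0.0565) or fetal remote 1 (0.114), and the fibroblast list (0.0375) without fetal infarct 1 or fetal remote 1 or 3 (0.0532 to 0.101). With the replicate number as a block the glycolysis and fatty acid lists had adjusted p = 0.0657 and 0.057. Over probes well above background on every array the cytokine (0.122), innate sensing (0.343) and fibroblast (0.0534) lists missed it, with normexp correction the innate sensing list (0.161) and in the deposited values antigen presentation (0.0518). Without a filter the fatty acid list missed it (0.0618), with quantile normalization (0.0718) or the mean of a gene's probes (0.0781) the glycolysis list, and against unnamed probes both (0.093 and 0.15).

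Adolescent infarct tissue was compared with adolescent sham (n = 3 and 2) to ask how the heart responds after birth. The genes named by fold were, on the lower side, of muscle contraction and energy supply and, on the higher side, of inflammation and cell division. No list of contractile genes was tested. MYH7, the slow myosin heavy chain of the ventricle, was 294-fold lower (log2 −8.20 ± 0.73, adjusted p = 1.14e-07), PRKAA2, a catalytic subunit of AMP-activated kinase, 173-fold (−7.44 ± 0.67, adjusted p = 1.25e-07) and PPARGC1A 138-fold (−7.11 ± 0.84, adjusted p = 1.99e-06). Above background on 1 of 3 infarct arrays, PRKAA2 and PPARGC1A were 130-fold and 56.8-fold lower at the limit. SLC2A4 was 121-fold lower (−6.92 ± 0.76, adjusted p = 8.86e-07), ENO3, the muscle enolase, 109-fold (−6.77 ± 0.57, adjusted p = 8.05e-08) and MB, myoglobin, 107-fold (−6.75 ± 0.67, adjusted p = 3.1e-07). Among the higher genes, LOC443321 was 124-fold (6.96 ± 1.34, adjusted p = 0.000283), CXCL8 116-fold (6.86 ± 1.04, adjusted p = 2.75e-05, 60.5-fold at the limit) and SLC11A1 57.9-fold (5.86 ± 1.24, adjusted p = 0.000648). IL6 was at least 23.9-fold higher (adjusted p = 9.16e-05), TYMS at least 23.7-fold (adjusted p = 2.39e-08) and CCNA2, a cyclin of DNA replication, at least 20.7-fold (adjusted p = 3.45e-08).

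In all 7182 of 12451 probes passed the threshold, 3196 higher and 3986 lower, among them 250 and 247 named genes. The sham arrays were dim (75th percentiles 242.9 and 128), as was adolescent border 3 (228.2), and the infarct arrays were among the brightest. With array brightness in the fit 1279 probes passed, and the calls of LOC443321, SLC11A1 and PPARGC1A were among 54 of 87 calls of named genes and list members that ended (PPARGC1A log2 −4.58, adjusted p = 0.0548). With normexp correction 20 of the 87 ended, that of IL6 among them (log2 1.22, adjusted p = 0.197). Leaving out 1 array ended the call of none of these 12 genes.

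Cell cycle transcripts rose in adolescent infarct. With an estimated correlation this list and the others called there had adjusted p = 0.544, or 0.576 for innate sensing. Their counts were the same adjusted over the list alone, except for 10 higher in innate sensing. Of 11 members 10 were higher, with a median of 2.63 log2 (camera, adjusted p = 1.44e-05). CCNB1 was 32.2-fold higher (log2 5.01 ± 0.41, adjusted p = 7.18e-08), CDK1, the kinase it activates, 21.8-fold (4.45 ± 0.40) and H2AZ1, a histone variant, 5.06-fold (2.34 ± 0.20).

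Several inflammation and matrix lists rose in adolescent infarct. Of 14 cytokines and chemokines 10 were higher and 2, CXCL1 and CXCL10, lower, with a median of 2.47 log2, or 2.09 at the bounds (camera, adjusted p = 0.018). IL10 was 14.4-fold higher (log2 3.85 ± 0.56, adjusted p = 1.9e-05), IL18 8.42-fold (3.07 ± 0.39) and IL1B at least 5.64-fold (adjusted p = 0.000247). Of 8 macrophage markers 7 were higher and TYROBP lower, with a median of 3.45 log2, or 3.31 at the bounds (camera, adjusted p = 0.0255), with CD14 at 12.4-fold (3.63 ± 0.56). Of 13 innate sensing members 9 were higher, with a median of 1.96 log2, or 1.67 at the bounds (camera, adjusted p = 0.0166), with TLR2 at least 29.9-fold. In the deposited values the cytokine (adjusted p = 0.0753), macrophage (0.0767) and innate sensing (0.0546) lists missed the threshold. Over probes well above background on every array they had adjusted p = 0.37, 0.0565 and 0.37. With normexp correction the cytokine (0.253) and innate sensing (0.622) lists missed it, IL1B turned to −0.50 (adjusted p = 0.582) and the calls of IL10 and TLR2 ended. With array brightness in the fit the calls of IL10, IL18, IL1B, CD14 and TLR2 ended (adjusted p = 0.0574 to 0.145).

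Of 11 extracellular matrix members 8 were higher in adolescent infarct, with a median of 2.88 log2 (camera, adjusted p = 0.00486). COL12A1 was 23-fold higher (log2 4.52 ± 0.46, adjusted p = 3.92e-07), COL3A1 8.67-fold (3.12 ± 0.74, adjusted p = 0.00163) and COL1A1 7.34-fold (2.88 ± 0.55, adjusted p = 0.000281). Of 13 proteases and inhibitors 9 were higher, with a median of 2.21 log2, or 1.93 at the bounds (camera, adjusted p = 0.00388), with TIMP1 at 19.7-fold (4.30 ± 0.72) and CTSB at 28-fold (4.81 ± 0.57). All 6 fibroblast markers were higher, with a median of 2.36 log2 (camera, adjusted p = 0.0255). The matrix (adjusted p = 0.0525) and fibroblast (0.0766) lists missed the threshold in the deposited values and the protease list with normexp correction (0.052). With array brightness in the fit the calls of COL3A1 (adjusted p = 0.167) and CTSB (0.058) ended.

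Energy lists fell. All 5 oxidative phosphorylation members were lower, with a median of −3.02 log2 (camera, adjusted p = 0.00227), with ATP5PO at 8.13-fold lower (log2 −3.02 ± 0.27, adjusted p = 1.2e-07). Of 7 fatty acid oxidation members 5 were lower and CPT1A, the liver form of the carnitine transferase, higher, with a median of −2.96 log2 (camera, adjusted p = 0.0445). CPT1B was 44.6-fold lower (−5.48 ± 0.42, adjusted p = 4.13e-08) and PPARA 7.78-fold (−2.96 ± 0.29, adjusted p = 3.04e-07). Of 10 glycolysis members 7 were lower and LDHA, SLC2A1 and PFKL higher, with a median of −2.06 log2 (camera, adjusted p = 0.027). The fatty acid list missed the threshold without adolescent infarct 3 (adjusted p = 0.0502) or adolescent sham 2 (0.0765), with the replicate number as a block (0.0649), without a filter (0.084), over probes well above background on every array (0.125) and against unnamed probes (0.0579). The glycolysis list missed it without a filter (0.0709). With normexp correction all 3 lists missed it (adjusted p = 0.103 for oxidative phosphorylation, 0.112 for fatty acid oxidation and 0.296 for glycolysis).

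The other lists were not past the threshold in adolescent infarct. In the hypoxia list EPAS1 and VEGFA were lower, VEGFA by 13.2-fold (log2 −3.72 ± 0.61, adjusted p = 5.5e-05), and 1 of the 4 members was higher (camera, adjusted p = 0.521). Of 13 angiogenesis members 3 were higher, among them ANGPT2, at least 5.25-fold, and 5 lower, among them FLT1 and TEK, receptors of endothelium (adjusted p = 0.637). Of 7 endothelial markers 3 were higher, PECAM1 at 3.07-fold, and 3 lower (adjusted p = 0.768). Of 4 fetal gene programme members CCN2, a matrix growth factor, was 15.1-fold higher (3.92 ± 0.69, adjusted p = 0.000113), and 3 were lower, MYH7 and CRYAB among them (adjusted p = 0.324). Of 16 developmental signalling members 5 were higher and 6 lower, BMP7 and FGF1 among them (adjusted p = 0.561). The antioxidant and iron list had adjusted p = 0.492. With array brightness in the fit the calls of CCN2, FLT1, BMP7 and FGF1 held, and those of EPAS1, VEGFA (−1.04, adjusted p = 0.504), ANGPT2, TEK, PECAM1 and CRYAB ended. Normexp correction turned ANGPT2 to −0.47.

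Among markers of other cells, 3 of 5 T and NK cell markers were lower in adolescent infarct, CD3E by 2.68-fold (log2 −1.42 ± 0.33, adjusted p = 0.00145, and camera adjusted p = 0.429 for the list). ITGB2 was 16.8-fold higher (4.07 ± 0.79, adjusted p = 0.000313) among 4 neutrophil markers (adjusted p = 0.786 for the list, median −0.19, mean 0.49, upward test). The adipocyte (adjusted p = 0.723), complement (0.768), antigen presentation (0.521), heat shock (0.55), skeletal muscle (0.521), interferon (0.858), mast cell (0.768) and erythroid (0.971) lists did not pass, and the erythroid list had a median of −0.29 with a mean of 0.21 and a downward test. With array brightness in the fit the calls of CD3E and ITGB2 ended.

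**Figure D2:**
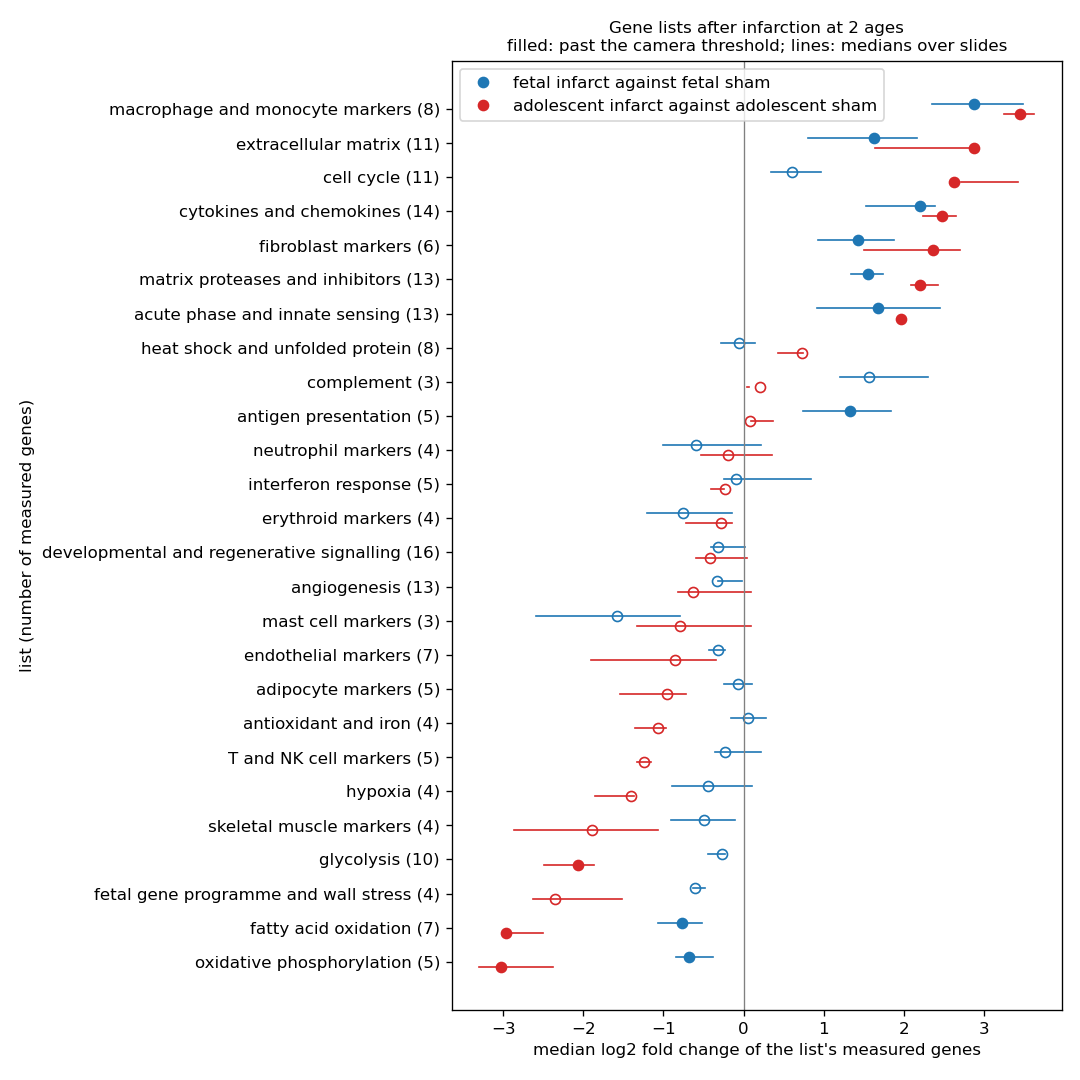
Median log2 fold change of the measured genes of each list (x axis) for the lists reported (y axis, number of genes in brackets), in fetal infarct against fetal sham (blue) and adolescent infarct against adolescent sham (red), with filled symbols for lists past the camera threshold and lines for the range of medians over slides. Cell cycle stood at 0.60 in the fetal and 2.63 in the adolescent comparison, and oxidative phosphorylation at −0.68 and −3.02.

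Adolescent border tissue was compared with adolescent sham (n = 3 and 2). Division, matrix and protease transcripts were higher there. TYMS was at least 11-fold higher (adjusted p = 6.33e-07), CCNA2 at least 7.25-fold (adjusted p = 5.36e-06), LOC443321 40.1-fold (log2 5.33 ± 1.34, adjusted p = 0.00856) and TIMP1 26.3-fold (4.72 ± 0.72, adjusted p = 0.000305). AQP4, a water channel, was 5.79-fold lower (−2.53 ± 0.46, adjusted p = 0.00117, 4.28-fold at the limit), DBP, a circadian transcription factor, 4.94-fold (−2.30 ± 0.32, adjusted p = 0.000128), PRKAA2 4.76-fold (−2.25 ± 0.67, adjusted p = 0.0208) and GNLY, a protein of cytotoxic granules, 4.56-fold (−2.19 ± 0.69, adjusted p = 0.0276). In all 3196 probes passed, 1577 higher and 1619 lower. The count was 1767 without adolescent border 1, 1737 without adolescent border 2, 1707 without adolescent sham 2 and 1812 without adolescent sham 3. It was 34 with normexp correction, 501 in a fit of these groups alone and 525 with array brightness in the fit.

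GNLY had adjusted p = 0.0749 without adolescent border 1, 0.0955 without adolescent border 2 and 0.365 (log2 −1.10) without adolescent sham 3. PRKAA2 had adjusted p = 0.0748 to 0.0946 without adolescent border 1 or 2 or adolescent sham 2 or 3, and LOC443321 had 0.0959 without adolescent sham 2. Normexp correction ended all of these named calls except that of TIMP1, array brightness in the fit those of LOC443321, AQP4, PRKAA2 and GNLY, and a fit of these groups alone those of PRKAA2 and GNLY.

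The cell cycle list rose in adolescent border, with 9 of 11 members higher, 9 also when adjusted over the list alone, and a median of 1.42 log2 (camera, adjusted p = 1.26e-06). Proteases (8 of 13, adjusted p = 0.000809), extracellular matrix (6 of 11, 0.00122) and fibroblast markers (4 of 6, 0.0221) rose, with the same counts adjusted over the list alone. So did cytokines (6 of 14, 7 alone, 0.02) and macrophage markers (6 of 8, 7 alone, 0.02). All 5 oxidative phosphorylation members were lower, 5 also when adjusted over the list alone, with a median of −1.21 log2 (0.00362). With an estimated correlation each of these 7 lists had adjusted p = 0.516. The cytokine (adjusted p = 0.157), macrophage and fibroblast (0.0653 for both) lists missed the threshold in the deposited values. The cytokine (0.615) and oxidative phosphorylation (0.0609) lists missed it with normexp correction, and the cytokine list also over probes well above background on every array (0.373).

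In remote muscle of infarcted adolescent hearts against adolescent sham (n = 3 and 2), 2 probes passed the threshold. Both were higher, and they were looked up after their values had been seen. They were an unnamed probe (log2 1.72 ± 0.19, adjusted p = 0.000682) and a probe of BAMBI, a decoy receptor of the TGF-beta family (1.65 ± 0.26, adjusted p = 0.0345), whose other probe stood at 0.91. An unadjusted p under 0.05 was reached by 1394 probes. The count was 155 without adolescent sham 2, 14 without adolescent sham 3, 1 without adolescent remote 1 and 50 with quantile normalization. No list passed the threshold.

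In adolescent infarct against adolescent remote muscle (n = 3 and 3), SLC2A5 was 41.2-fold higher (log2 5.37 ± 0.98, adjusted p = 0.000149), IL6 37.8-fold (5.24 ± 0.98, adjusted p = 0.000184, 26.4-fold at the limit), ASPM, a protein of the mitotic spindle, 33-fold (5.05 ± 0.56, adjusted p = 7.77e-07, 14.7-fold at the limit) and PLAUR 32.6-fold (5.03 ± 0.76, adjusted p = 2.25e-05). MYH7 was 218-fold lower (−7.77 ± 0.65, adjusted p = 3.72e-08), ENO3 147-fold (−7.20 ± 0.51, adjusted p = 9.93e-09), PPARGC1A 129-fold (−7.01 ± 0.75, adjusted p = 5.19e-07, 52.9-fold at the limit) and SLC2A4 122-fold (−6.93 ± 0.68, adjusted p = 1.88e-07). In all 7132 probes passed, 3417 higher and 3715 lower, with 3567 under normexp correction, which ended the call of ASPM (adjusted p = 0.136), and 3968 with array brightness in the fit. All 11 cell cycle members were higher, 11 also when adjusted over the list alone, with a median of 3.57 log2 (camera, adjusted p = 5.5e-06, and adjusted p = 0.523 with an estimated correlation). Lists of cytokines, innate sensing, proteases, matrix, macrophage and fibroblast markers were higher and the 3 energy lists lower, with camera adjusted p from 0.00196 to 0.0436 and adjusted p = 0.523 with an estimated correlation. The macrophage list missed the threshold without adolescent infarct 1 or 3 or adolescent remote 2 or 3 (0.055 to 0.0785), and the fibroblast list without adolescent infarct 1 or 2 or adolescent remote 1 or 2 (0.0572 to 0.0646). In the deposited values the cytokine and innate sensing (0.0787 for both), macrophage (0.101) and fibroblast (0.0904) lists missed it, and over probes well above background on every array these 4 and the fatty acid list (adjusted p = 0.0735 to 0.367). Normexp correction ended the innate sensing (0.364), fatty acid and glycolysis calls (0.0561 for both). The fatty acid list also missed it with the replicate number as a block (0.0641), without a filter (0.0504) and against unnamed probes (0.0586), the macrophage list with quantile normalization (0.0734), and the macrophage and fibroblast lists with the stricter filter (0.0622).

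**Figure D3:**
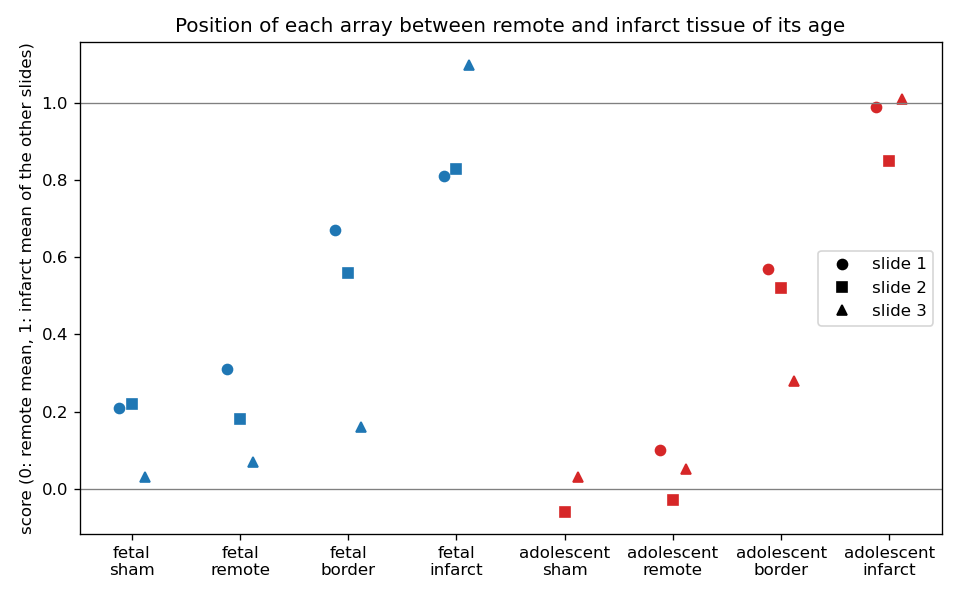
Position of each array (y axis) on the line from the mean of remote arrays (0) to the mean of infarct arrays (1) of its age, taken from the other slides, by group (x axis), with circles, squares and triangles for slides 1, 2 and 3. The border arrays of slide 3 scored 0.16 (fetal) and 0.28 (adolescent), and the other border arrays 0.52 to 0.67.

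The difference between the ages in the response to infarction was tested as the adolescent minus the fetal log2 fold change (n = 3, 2, 3 and 3). CCNA2 differed by a fitted 5.69 ± 0.60 log2 (adjusted p = 3.27e-05), TYMS by 4.56 ± 0.47 (adjusted p = 3.11e-05) and ASPM by 4.47 ± 0.84 (adjusted p = 0.00134). These were not above background in adolescent sham, so the differences are only known to be at least 3.87, 3.15 and 2.70. The most negative named values were MYH7 with −7.10 ± 0.98 (adjusted p = 0.000178), PRKAA2 with −6.26 ± 0.90 (adjusted p = 0.000227, −5.85 at the limit), PPARGC1A with −5.21 ± 1.13 (adjusted p = 0.00338, −3.93 at the limit), ENO3 with −5.21 ± 0.76 (adjusted p = 0.000254) and MB with −5.15 ± 0.89 (adjusted p = 0.000737). The largest positive values, SERPINA1 (8.04 ± 2.13, adjusted p = 0.0111) and AHSG (7.54 ± 1.99, adjusted p = 0.0111), go at least in part with the liver transcripts of the fetal sham arrays (AHSG at 7.29 log2 on fetal sham 1). AHSG was above background in neither adolescent group (6.09 at the limit), and SERPINA1 not in adolescent sham (5.74). In all 3103 probes passed, 1291 higher and 1812 lower, with 2037 without adolescent sham 3, 74 with normexp correction and 2 with array brightness in the fit. Array brightness ended the calls of all 10 genes. Normexp correction ended those of SERPINA1, AHSG, CCNA2, TYMS, PPARGC1A and MB and turned ASPM to −0.07. In the deposited values SERPINA1 (adjusted p = 0.0856) and PPARGC1A (−0.56, adjusted p = 0.364) missed the threshold.

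Of the 11 cell cycle members 9 had a higher response in adolescent hearts, 10 when adjusted over the list alone, with a median difference of 2.37 log2 (camera, adjusted p = 7.99e-09, and adjusted p = 0.258 with an estimated correlation). All 5 oxidative phosphorylation members had a lower one, 5 also when adjusted over the list alone, with a median of −2.34 (adjusted p = 0.000743, and adjusted p = 0.563 with an estimated correlation). Of 10 glycolysis members 6 had a lower and 1 a higher response, 7 and 1 when adjusted over the list alone, with a median of −1.56 (adjusted p = 0.026, and adjusted p = 0.597 with an estimated correlation). The glycolysis list missed the threshold without adolescent sham 2 (adjusted p = 0.0691) and with normexp correction (0.221), and the oxidative phosphorylation list with normexp correction (0.126). The extracellular matrix list did not pass (adjusted p = 0.0932), though it did without adolescent infarct 3, adolescent sham 2, fetal infarct 1 or fetal sham 3 (0.0162 to 0.048) and without a filter (0.0332). No difference between the ages passed for macrophage markers (adjusted p = 0.767), cytokines (0.656), fibroblast markers (0.285), fatty acid oxidation (0.182), the fetal gene programme (0.285) or skeletal muscle markers (0.711).

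Over all probes the infarct responses of the ages ran in parallel. The fold changes had Pearson r = 0.707 and Spearman rho = 0.694 across 12451 probes, which are not independent replicates. Both ages called 1851 probes, 1031 higher and 809 lower in both and 11 in opposite directions, where 302 and 305 would be shared by chance. The shared number was 729 without fetal infarct 3, 997 without fetal sham 3, 1069 without fetal sham 1, 762 with array brightness in the fit and 184 (165 higher, 19 lower) with normexp correction. Along a line through the origin, adolescent fold changes were 1.40 times the fetal ones, 1.01 times with array brightness in the fit and 2.23 times with normexp correction.

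In border tissue 229 probes differed between the ages in their response, 191 higher and 38 lower (n = 3, 2, 3 and 3). CCNA2 differed by a fitted 4.84 ± 0.60 log2 (adjusted p = 0.000463), TYMS by 4.25 ± 0.47 (adjusted p = 0.000196), ASPM by 3.73 ± 0.84 (adjusted p = 0.0309), HBB, a hemoglobin chain, by 3.87 ± 0.94 (adjusted p = 0.0448, other probe not past the threshold) and AHSG by 8.36 ± 1.99 (adjusted p = 0.0411). All of these but HBB were not above background in adolescent sham. With that group raised to the background limit CCNA2, TYMS and ASPM differed by at least 3.02, 2.85 and 1.96, and AHSG stood at 6.70. TUBA4A, a tubulin, differed by −1.99 ± 0.41 (adjusted p = 0.0209), DBP by −1.95 ± 0.42 (adjusted p = 0.027), ATP5MC1 by −1.25 ± 0.32 (adjusted p = 0.0498, 0 of 3 other probes past the threshold), ALDOA, an aldolase, by −1.25 ± 0.30 (adjusted p = 0.0416) and CTNNBL1 by −1.23 ± 0.28 (adjusted p = 0.0309). The count was 1272 without adolescent border 3 and fell to 61 without fetal border 3 and to 63 to 143 without fetal border 2, fetal sham 1 or 3, adolescent border 1 or 2, or adolescent sham 2 or 3. Of the 10 named calls, 8 ended without adolescent border 1, adolescent border 2, adolescent sham 3 or fetal border 3, 7 without adolescent sham 2 or fetal sham 3, 5 without fetal border 2, fetal sham 1 or fetal sham 2 and 1 without fetal border 1. The count was 0 with normexp correction, which ended all 10 calls, 8 in a fit of these groups alone, which ended all but that of TYMS, and 15 with array brightness in the fit, which ended all but those of CCNA2 and TYMS. The calls of ALDOA and ATP5MC1 also ended in the deposited values, without a filter and with quantile normalization, those of AHSG in the first 2, of ASPM in the first and of HBB in the second, and that of ATP5MC1 with the replicate number as a block (adjusted p = 0.0654).

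The cell cycle list differed between the ages in border tissue, with a median of 1.39 log2 and 5 of 11 members higher, 8 when adjusted over the list alone (camera, adjusted p = 1.25e-09, and adjusted p = 0.195 with an estimated correlation). The oxidative phosphorylation list had a median of −1.21 with 1 of 5 members lower, 5 when adjusted over the list alone (adjusted p = 0.00265, and adjusted p = 0.62 with an estimated correlation), and missed the threshold in the deposited values (0.0827). The extracellular matrix list had a median of 1.05 with no member past the threshold, 2 when adjusted over the list alone (adjusted p = 0.0332, and adjusted p = 0.779 with an estimated correlation). It missed the threshold without adolescent border 2, adolescent sham 3, fetal border 3 or fetal sham 2 (0.0819 to 0.214), with quantile normalization (0.0525), in the deposited values (0.255) and by fry (0.249).

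In remote muscle 1 probe differed between the ages in its response, the unnamed probe higher in adolescent remote (1.83 ± 0.26 log2, adjusted p = 0.0169), with 862 at an unadjusted p under 0.05 (n = 3, 2, 3 and 3). The count was 0 without fetal remote 1, fetal remote 2, fetal remote 3, fetal sham 3 or adolescent remote 2, and rose to 2 without fetal sham 1, fetal sham 2 or adolescent remote 3, 5 without adolescent sham 3 and 9 without adolescent sham 2. The cell cycle list had a median of 0.36, or 0.32 at the bounds, with no member past the threshold, 3 when adjusted over the list alone (camera, adjusted p = 0.00111, and adjusted p = 0.945 with an estimated correlation). It missed the threshold without adolescent sham 2 (0.158) or fetal sham 3 (0.0694), with normexp correction (0.757), over probes well above background on every array (0.273) and by fry (0.857).

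Adolescent and fetal sham hearts were compared to give the baseline of each age (n = 2 and 3). Fetal hearts held more hemoglobin transcripts, HBG, described on the array as a fetal hemoglobin chain, being 540-fold lower in adolescent sham (log2 −9.08 ± 0.63, adjusted p = 7.73e-08, 300-fold at the limit, above background on 1 of 2 adolescent arrays) and HBB 404-fold (−8.66 ± 0.70, adjusted p = 3.39e-07), whose other probe was lower but not past the threshold. AHSG was at least 203-fold lower (adjusted p = 0.000206), with the levels of the fetal sham arrays given above, and CATHL1B, an antimicrobial peptide of granulocytes, at least 27.3-fold (adjusted p = 7.85e-05). GNLY was 103-fold higher in adolescent sham (6.69 ± 0.69, adjusted p = 3.53e-06), ITGB6, an epithelial integrin chain, 53.8-fold (5.75 ± 0.63, adjusted p = 5.88e-06), SAA3, an acute phase protein, 29.2-fold (4.87 ± 1.06, adjusted p = 0.00239) and TUBA4A 24-fold (4.58 ± 0.31, adjusted p = 6.74e-08). In all 3736 probes passed, 1882 higher and 1854 lower, with 2092 without adolescent sham 3, 2443 in a fit of these groups alone, 90 with normexp correction and 506 with array brightness in the fit. Normexp correction ended the calls of AHSG, CATHL1B, GNLY, ITGB6 and SAA3, and array brightness those of AHSG and SAA3.

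The cell cycle list was lower in adolescent sham, with 10 of 11 members lower, 10 also when adjusted over the list alone, and a median of −1.77 log2 (camera, adjusted p = 1.1e-08, and adjusted p = 0.135 with an estimated correlation). CCNA2 was at least 10.9-fold lower and TYMS at least 5.94-fold. Of 4 erythroid markers 3 were lower, 3 also when adjusted over the list alone, with a median of −6.38 (adjusted p = 0.00228, and adjusted p = 0.0603 with an estimated correlation). Of 11 extracellular matrix members 7 were lower, 8 when adjusted over the list alone, with a median of −1.61 (adjusted p = 0.00431, and adjusted p = 0.582 with an estimated correlation), with adjusted p = 0.0529 in the deposited values.

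The T and NK cell, antigen presentation and oxidative phosphorylation lists were higher in adolescent sham, and those of cytokines (adjusted p = 0.794), innate sensing, fatty acid oxidation and glycolysis (0.494 for each) did not pass. Of 5 T and NK cell markers 4 were higher, 5 when adjusted over the list alone, with a median of 1.93 log2 (camera, adjusted p = 0.00228, and adjusted p = 0.279 with an estimated correlation), with CD3E, a chain of the T cell receptor complex, 12.1-fold higher (3.60 ± 0.33, adjusted p = 9.48e-07). Of 5 antigen presentation members 4 were higher, 4 also when adjusted over the list alone, with a median of 1.72 (adjusted p = 0.0144, and adjusted p = 0.527 with an estimated correlation). Without adolescent sham 3 that list missed the threshold (adjusted p = 0.0548). Of 5 oxidative phosphorylation members 4 were higher, 4 also when adjusted over the list alone (camera, adjusted p = 0.0433, and adjusted p = 0.582 with an estimated correlation). This last list missed the threshold without adolescent sham 3 (0.0751) or fetal sham 1 (0.0523) and under 9 other settings, with adjusted p up to 0.49.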

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

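The tests of dim arrays, array brightness, other cell types, single arrays, fetal sham 2 and 3 and slide 3 were chosen only after the results were seen, and the rule for the brightness test was made stricter after its value was known. The test of liver tissue and the splits of the arrays were chosen before. The age differences given here stood out because the response differed between fetal and adolescent hearts by a test of the difference itself. The scores of slide 3 and the splits come from no such test.

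Transcripts of liver secreted proteins stood high in fetal sham hearts. They entered age differences of SERPINA1 (8.04 log2, 5.74 at the limit, fetal change −5.43) and AHSG (7.54) in infarct and AHSG (8.36) in border. AHSG was 7.29, 0.25 and 2.53 on fetal sham 1, 2 and 3, ALB 3.81, −2.99 and 0.06 and TTR 2.42, −5.30 and −1.79, against fetal zone means of −5.49, −5.37 and −5.60. If liver tissue or liver RNA were in these samples, other liver genes would be higher too, and 5 others were by a median of 1.25 log2 (F2 1.67, F9 1.25, SERPINC1 0.19, IGFBP1 2.09 and CYP3A24 0.65), while APOA1, already seen, was lower (−0.47). Without fetal sham 1 that median was 0.43, with 1 of the 5 well above background on both other arrays, so these genes decide little for fetal sham 2 and 3. A single array is argued against, as without fetal sham 1 AHSG was 7.35 ± 1.09 log2 above fetal remote (adjusted p = 0.0225). SERPINA1 (−2.35) and SPP2 (−3.14) also exceeded the zone means (−6.78 and −7.40) on fetal sham 3. Liver RNA may be the source on fetal sham 1 and stays open on the others. A difference in the hearts was not tested.

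Some transcripts of muscle and energy supply lost more in adolescent than in fetal infarct, with age differences of −7.10 log2 for MYH7, −6.26 for PRKAA2 (−5.85 at the limit), −5.21 for both PPARGC1A (−3.93) and ENO3 and −5.15 for MB. The oxidative phosphorylation list had a median of −2.34 and the glycolysis list of −1.56, while fatty acid oxidation did not pass (adjusted p = 0.182) and no list of contractile genes was tested. Dim adolescent sham arrays are argued against. Infarct against remote gave a median age difference of −1.63 over 24 members of 4 lists (−1.87, −1.48 and −1.52 by slide). Macrophage markers 4.30 log2 above endothelial markers (SDs 1.70 and 1.91) argue only against a like rise of all cell types other than muscle. A loss of muscle cells stays open. With array brightness in the fit the median went from −2.21 to −1.10 (SD 1.93) and the median SE from 0.55 to 0.79. Members called lower went from 16 to 0 and members under 0 from 19 to 18. Brightness and age by zone cannot be told apart, as brightness follows the groups, and age itself stays open.

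Border arrays of slide 3 lay nearer to remote tissue than the other border arrays, at 0.16 (fetal) and 0.28 (adolescent) on the line from remote (0) to infarct (1) against 0.52 to 0.67. They enter the border age differences. An equal shift of slide 3 is argued against by its infarct arrays, at 1.01 or more. Fetal remote 3 (0.07) and sham 3 (0.03) also lay below slides 1 and 2 (0.18 to 0.31). Dim arrays are argued against by scores up to 0.28 over probes well above background on every array. A fetal slide effect and a biopsy farther from the infarct, not tested, stay open.

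Probes with a different response numbered 3103 in infarct, 229 in border and 1 in remote muscle. In infarct CCNA2 differed by a fitted 5.69 log2, TYMS by 4.56 and ASPM by 4.47, which against an adolescent sham group at background are at least 3.87, 3.15 and 2.70, and the cell cycle list by a median of 2.37. In border CCNA2 differed by 4.84 (at least 3.02), TYMS by 4.25 (at least 2.85), HBB by 3.87, ASPM by 3.73 (at least 1.96), TUBA4A by −1.99, DBP by −1.95, ATP5MC1 by −1.25, ALDOA by −1.25 and CTNNBL1 by −1.23. List medians there were −1.21 for oxidative phosphorylation, 1.39 for the cell cycle and 1.05 for extracellular matrix, and in remote muscle 0.36 for the cell cycle.

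Splits of the 6 arrays of a comparison into other groups of 3 number 10, too few for a share under 0.05. In fetal infarct against sham 1 of the 10 splits, the real 1, gave 2131 probes and the highest other 0. In fetal infarct against remote these were 1, 2169 and 0, and in adolescent infarct against remote 1, 7132 and 0. In fetal border against sham 2 splits gave as many as the real 2 probes, with 11 as the highest other. In fetal remote against sham 2 splits did, with 222 in the split that set fetal remote 1, fetal sham 1 and fetal sham 3 against the rest, which points to a structure of these samples. Where the numbers pair, in the 4 fetal comparisons, the 3 other splits that part all 3 pairs, as the real one does, gave 0 probes each. The other 6, those with 11 and 222 among them, part 1 pair and keep 2 whole. With the number as a block the real split gave 4 probes in fetal remote and 2 in fetal border.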

How the results depend on the processing

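The alternatives were chosen before the data were examined, except the fit with array brightness, the filter for probes well above background on every array and the unnamed probes as background of the list tests, which were added after the data had been seen. Where a value moved, the cause was not tested unless fewer probes or arrays show it. Of the 94 calls of genes named by rank or from the fixed set, 92 held their direction and side of the threshold with quantile normalization, 91 with the stricter filter, 87 without a filter, 76 in the deposited values and 75 in fits of the compared groups alone. Signal over background was low on adolescent sham 3 (60.99% of probes well above background), border 3 (64.38%), remote 3 (66.1%) and sham 2 (69.2%), which limits the values of dim genes there.

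Normexp background correction gave 189 probes in fetal infarct, 0 in fetal border (157 at an unadjusted p under 0.05 by limma) and 0 in fetal remote against sham (79), 140 in fetal infarct against remote, 34 in adolescent border, 0 in adolescent remote (136) and 3567 in adolescent infarct against remote. Age differences numbered 74 in infarct, 0 in border (122) and 0 in remote (56), and the shams differed in 90. It kept 41 of the 94 calls. It reversed CD247 in fetal infarct to −0.15, NGN3 to 0.08, ASPM in the age difference to −0.07, IL1A in adolescent border to −0.24 and, in adolescent infarct, ANGPT2 to −0.47, HIF1A to −0.43, ICAM1 to −0.08, IL1A to −0.59, IL1B to −0.50, PTX3 to −0.54 and SELP to −0.60.

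With array brightness as a covariate 1279 probes passed in adolescent infarct, 3968 against remote, 525 in adolescent border, 1 in adolescent remote and 0 in fetal border (1150 unadjusted, limma). Age differences numbered 2 in infarct, 15 in border and 0 in remote (495), the shams differed in 506, and 61 of the 94 calls held. FTH1 in adolescent infarct reversed to 0.21 and ATP5PD between shams to −0.35. Over probes well above background on every array, limma gave 0 in fetal border (708 unadjusted), fetal remote (139), adolescent remote (941) and the remote age difference (607), with 44 of the 94 calls held among fewer probes.

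In the deposited values fetal border had 0 (780), fetal remote 1 and the remote age difference 0 (594), FTH1 in adolescent infarct reversed to 0.84 and ATP5MC1 between shams to −0.11. Quantile normalization gave 50 in adolescent remote and 0 in the remote age difference (1060), with FTH1 at 0.29. Without a filter fetal border had 0 (985), adolescent remote 1 and the border age difference 147. A fit of the compared groups alone gave 1 in fetal border, 0 in fetal remote (251), 1423 in fetal infarct against remote, 501 in adolescent border, 0 in adolescent remote (1314), 8 and 0 (1045) in the border and remote age differences and 2443 between shams. Trend and robust variances gave 1 in adolescent remote and 370 and 0 (852) in the border and remote age differences. Array weights, from 0.28 to 6.96, gave 3223 in fetal infarct, 1027 in fetal border, 3298 in fetal infarct against remote, 1 in adolescent remote and 1700 in the border age difference. A fold of at least 2 left 1231 in fetal infarct, 1257 against remote, 2048 in adolescent border and 2415 between shams.

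With the replicate number as a block fetal remote had 4 probes. Past the threshold no longer by limma were ATP5MC1 in the border age difference (adjusted p = 0.0654), NDUFA2 in fetal infarct (0.0517) and HIF1A in adolescent infarct (0.07). In the list tests these were fatty acid oxidation in each infarct comparison within an age (0.0525 to 0.0649), glycolysis in fetal infarct against remote (0.0657, random block 0.0513) and oxidative phosphorylation between shams (0.0741, random block 0.0529). The block changed no other call of a named gene or list described.

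Leaving out 1 array at a time gave 820 to 1828 in fetal infarct, 0 to 125 in fetal border, 0 to 13 in fetal remote, 727 to 1770 in fetal infarct against remote, 5794 to 6802 in adolescent infarct, 1707 to 4266 in adolescent border, 1 to 155 in adolescent remote and 6461 to 6692 in adolescent infarct against remote. Age differences ran from 2037 to 3171, 61 to 1272 and 0 to 9, and the shams from 2092 to 3229. Of the 94 calls 81 to 93 held, and 65 to 71 list tests were called against 68. With an estimated correlation 0 list tests were called by camera.

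The similarity of the ages (r = 0.707) was 0.787 with normexp correction, 0.776 in the deposited values, 0.681 without a filter, 0.749 over probes well above background on every array, 0.639 with brightness and 0.659 to 0.725 with 1 array left out.

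The share of called probes that were higher moved by over 10 points under some scalings. With normexp correction it went from 55.2% to 88.9% in fetal infarct, from 55% to 90% against remote, from 44.5% to 19.8% in adolescent infarct, from 49.3% to 100% in adolescent border, from 41.6% to 14.9% in the infarct age difference and from 50.4% to 36.7% between shams. In the deposited values it was 53.8% and 51.7% (83.4% before) in the infarct and border age differences, with brightness 76.2% in adolescent border and 39.7% between shams, and with quantile normalization 68% in adolescent remote. The median over all probes in adolescent infarct was −0.19, and −1.06 with normexp correction, −0.03 with quantile normalization and 0.02 in the deposited values.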

Other observations

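The tests in this part were all chosen after the results were seen. Hemoglobin transcripts rose in adolescent border tissue. HBB was 4.06 ± 0.70 log2 above adolescent sham (adjusted p = 0.000824, n = 3 and 2). HBG was 3.26 ± 0.63 higher (adjusted p = 0.00178, 2.41 at the limit). Whether the probes tell globins apart was not tested. HBB stood at 1.51, 3.43 and 2.30 on the border arrays, −1.72 and −1.56 on the sham arrays, −1.49, −0.52 and 0.54 on the remote arrays and −2.74, −0.17 and −1.92 on the infarct arrays. AHSP, a chaperone of hemoglobin in red cell precursors, was at −0.27 in the same comparison. All fetal arrays held HBB at 5.77 to 7.93.

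Cathelicidins, peptides of granulocytes, set the ages apart more than the zones. CATHL1B and CATHL3 were well above background on all 12 fetal arrays and on no adolescent array. In the sham comparison CATHL3 was at least 17.3-fold lower in adolescent hearts (adjusted p = 0.00082). In fetal infarct against sham neither passed the threshold (CATHL1B −0.87 ± 0.88 log2, adjusted p = 0.544, and CATHL3 −0.91 ± 0.94, adjusted p = 0.555). Against fetal remote they were lower on all 3 slides and missed it too (−1.90 ± 0.88, adjusted p = 0.147, and −2.03 ± 0.94, adjusted p = 0.148).

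Cell cycle transcripts were lower in adolescent than in fetal sham hearts (median −1.77 log2) and rose in adolescent infarct. Over the 11 members adolescent infarct stood a median of 0.92 log2 (SD 0.78) above fetal sham, with limma calling 5 higher and 0 lower. Its untested gaps to fetal infarct ran from PCNA (2.03 against 1.25) to HMGB2 (3.14 against 3.56). No explanation or cell of origin was tested.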
